A study of Homo sapiens with 4 samples.

How the data were processed

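Each of the 4 samples, 2 infected with HCV and 2 mock-infected, gave 1 array, and groups and replicate numbers were taken from the sample labels. Total RNA was purified on columns, reverse transcribed with an oligo(dT) primer carrying a T7 promoter and transcribed into cRNA with Cy3, per the labels' protocols. Arrays of design 039494 were read with Agilent Feature Extraction, version 11.5 per the submitters' processing notes and 11.5.1.1 per the file headers. The deposited scanner files hold, per the file headers, a mean intensity, a background intensity and a processed intensity (background-subtracted by the software, linear, not scaled between arrays) for each of 58717 spots and 4259 control spots. The authors' series matrix table is a second deposited table of intensity values. For all 50599 probes on each array its values equalled the mean processed signal over the spots of a probe within 0.01%, so it is linear and unscaled, and it is not an independent source. Its medians were 12.7 for HCV 1, 16.2 for HCV 2, 13.7 for mock 1 and 4.87 for mock 2. All arrays were on 1 slide in 1 scan, so no batch could be tested.

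Control spots and spots with an outlier flag were left out, 291 to 398 such spots per array. Spots of a probe were averaged on the log2 scale, and each array's 75th percentile was subtracted. A probe was tested if well above background (on at least 0.5 of its spots) on both arrays of at least 1 group. For each gene name the probe with the highest mean over the 4 arrays was used. Probes were named through their RefSeq accession where the gene table held it (28174 of 50599 probes, 4387 with an updated symbol), and otherwise kept the name in the file. Coordinates are those of the files (hg19); exons and UTRs were not analysed here. The precision is limited by the number of arrays, and mock 2 had a lower signal over background than the others.

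Infected and mock arrays were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over 19347 genes and a threshold of 0.05. The residual degrees of freedom were 2, with 6.21 added by the prior. Where a gene was above background in 1 group only, "at least N-fold" sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Those folds are on the scale of the 75th percentile. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. Of 799 list entries, 702 were matched to a tested gene. Tested on simulated data for this comparison (4 arrays, 19347 genes), limma called 48 of 50 genes changed by 6 log2 units, 43 of 50 by 4, 2 of 50 by 2 and 0 of 50 by 1, with 9 false calls. In a simulation of 20 lists of 30 genes, camera called the 1 list shifted by 1.5 log2 units and 0 of the others. Both simulations drew genes independently, with the same spread on all arrays. They therefore do not show error rates for correlated genes or unequal spread, or whether smaller list shifts would be called.

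The comparison, the lists, the rule for naming genes and the alternatives not named as added were fixed before the data were examined. The text names the 12 genes each way with the largest difference among those past the threshold, with a RefSeq mRNA accession or a symbol, above background on all 4 arrays and with no overlap between the groups. It names 5 non-coding transcripts each way by the same rule, 3 genes each way by the largest lower bound of the fold, and the 4 members of a list with the smallest p. Not all of these list members are named: for lists described only by their values none is, a choice made after the values were seen, and 1 further result is not reported. Places left open by the threshold went to the smallest p, as values only. Alternative settings were normexp with offset 50 and quantile scaling, quantile scaling, median centring, the series matrix, no filter and a stricter filter on dim probes, other rules for several probes per gene, a variance trend, a robust prior, the replicate number as a block, and leaving out each array. Cyclic loess, a correction for probe GC content (loess with span 0.3), leaving out probes that match Alu or ribosomal RNA, and crossed pairs were added after seeing the data. A probe counted as matching Alu if it shared at least 3 stretches of 12 bases with a general AluY consensus or its reverse complement. A probe counted as matching ribosomal RNA by its gene name alone, without a comparison of sequences.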

Results

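The series compared Huh7.5 cells infected with hepatitis C virus (HCV) with mock-infected cells. Huh7.5 is a line derived from human hepatoma cells that carries a defective RIG-I and takes HCV readily. The virus was JFH-1, an isolate that replicates in cell culture. Total RNA was taken 48 h after infection from 2 infected and 2 mock samples. Each sample was hybridised to 1 Agilent array in 1 colour, with 58717 spots for human transcripts, including long non-coding RNAs. The labels do not say whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. With 2 samples against 2, an exact two-sided permutation test of a single value cannot go below p = 0.33.

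Signal over background differed between the arrays. Well above background were 53.78% of the spots on HCV 1, 60.01% on HCV 2, 55.16% on mock 1 and 40.86% on mock 2. The 75th percentile of the processed signal was 120 and 146 on the infected arrays, 131 on mock 1 and 29.1 on mock 2, and no spot was saturated. After scaling, the median SD of a gene was 0.26 log2 units between the infected arrays and 0.47 between the mock arrays (n = 2 each). The scaled log2 values of HCV 1 and HCV 2 correlated over genes with r = 0.969, those of mock 1 and mock 2 with r = 0.939, and those of arrays from different groups with r from 0.905 to 0.951. Genes are not independent replicates. The median gene lay 0.25 log2 units lower in infected than in mock cells (-0.25) on the scale used, so differences of genes and lists are given relative to the median gene unless stated. The limma p-values of single genes, also those adjusted over a list alone, test the difference before the median gene is subtracted. Genes called lower therefore include the -0.25 shift of the median gene.

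The comparison of infected with mock cells asks which host transcripts differ 48 h after infection. Of 19347 genes tested, 5 were higher and 2 were lower in infected cells (limma, Benjamini-Hochberg adjusted p below 0.05). NKX2-5, a homeobox transcription factor of heart development, showed the smallest p. Its mean log2 signal was 7.19 ± 0.06 in infected and 1.61 ± 0.04 in mock cells (SD, n = 2 each), a log2 difference of 5.58 (SE 0.45, adjusted p = 0.0253), or 5.84 relative to the median gene. C18orf23, a predicted non-coding transcript, rose by 5.66 relative to the median gene, from 1.55 ± 1.11 to 6.95 ± 0.20 (adjusted p = 0.0475). CISD3, a mitochondrial iron-sulfur protein, rose by 5.27, from 0.90 ± 0.97 to 5.92 ± 0.16 (adjusted p = 0.0475). The lincRNA XLOC_002736 was well above background on both infected arrays and on neither mock array. On the scale used it was at least 21.2-fold higher in infected cells (adjusted p = 0.0475). The difference of XLOC_002736 relative to the median gene ran from 2.42 to 6.03 over the settings. FAM177B, a protein-coding gene, was well above background on both mock arrays and on neither infected array. On the scale used it was at least 30.5-fold lower in infected cells (adjusted p = 0.036). The difference of FAM177B relative to the median gene ran from -7.03 to -1.93 over the settings. The other lower transcript was the lincRNA XLOC_002730, at 2.16 ± 0.78 in infected and 9.40 ± 1.69 in mock cells, a difference of -6.98 relative to the median gene (adjusted p = 0.0475). The fifth higher feature was the unnamed probe A_33_P3321682, reported because it completes the count and chosen after its values were seen. It rose from 1.79 ± 0.47 to 6.10 ± 0.11 (adjusted p = 0.0475). All 7 differed by at least 2-fold, and both infected arrays lay on the same side of both mock arrays for each.

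**Figure D1:**
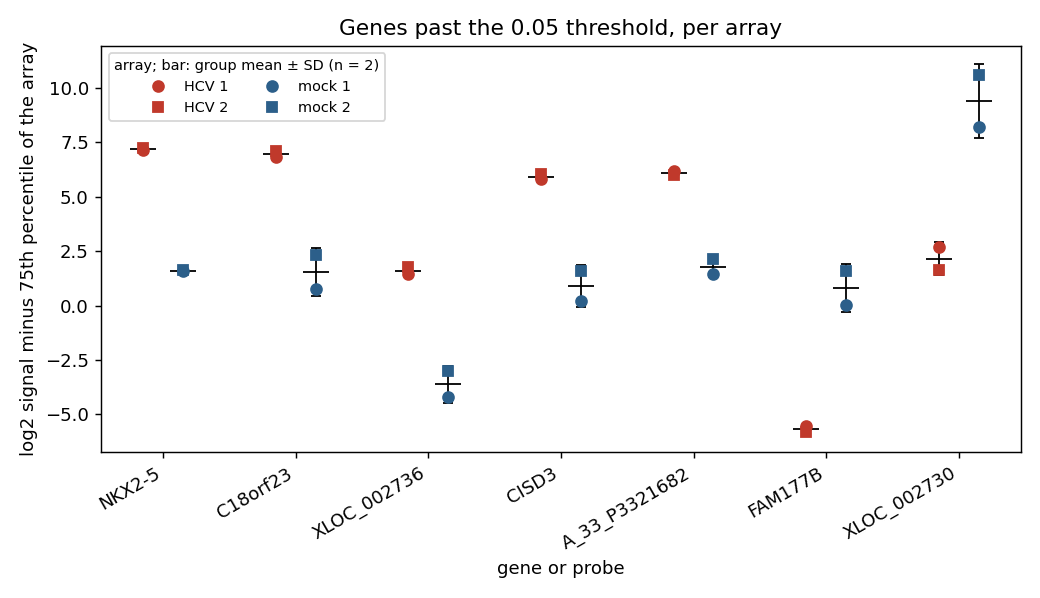
Scaled log2 signal (vertical axis, log2 processed signal minus the array's 75th percentile) of the 7 features past the threshold, with 1 point per array and bars for the group mean ± SD (n = 2). NKX2-5 sits at 7.15 and 7.24 on the infected arrays and at 1.58 and 1.63 on the mock arrays, and XLOC_002730 shows the widest mock spread, 8.20 and 10.59.

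In hg19 coordinates, as the files give them, the NKX2-5 probe lies on chromosome 5 at 172659138 to 172659197. The C18orf23 probe is on chromosome 18 at 43914943 to 43915002 and the CISD3 probe on chromosome 17 at 36891334 to 36891393. XLOC_002736 was measured on chromosome 3 at 98700171 to 98700230, and XLOC_002730 on the same chromosome at 96336291 to 96336350. The FAM177B probe lies on chromosome 1 at 222923479 to 222923538, and A_33_P3321682 on chromosome 2 at 236673283 to 236673342. NKX2-5, C18orf23, CISD3, FAM177B and A_33_P3321682 had no further tested probe. The other probe of XLOC_002736 that was tested gave a log2 difference of 0.49 (SE 0.52), before the median gene is subtracted. The 3 further probes of XLOC_002730 gave -3.32 (SE 0.49), -4.95 (SE 0.55) and -4.69 (SE 0.53), the last 2 also past the threshold when every probe was tested by itself (adjusted p = 0.0474 each).

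How many genes passed depended on scaling, filter and arrays. At an unadjusted p below 0.05, 2905 genes were counted (1367 higher, 1538 lower), against 967 expected by chance, and 177 genes had an adjusted p below 0.1 (95 higher, 82 lower). With limma, no gene passed after quantile scaling (1671 higher and 1055 lower at an unadjusted p below 0.05), after median centring (1462 and 1196), after normexp background correction with quantile scaling (1601 and 1404) or without a filter on dim probes (756 and 1664), and 1 higher and no lower gene did after cyclic loess. Testing only probes above background on all 4 arrays gave 43 higher and 50 lower genes, a variance trend gave 168 and 174, and a correction for probe GC content 35 and 30. Each array left out raised the counts, but the lone array left in a group is then assumed to vary like the other group. Without a mock array the spread rests on the infected pair (median SD 0.26 log2 units), and without an infected array on the mock pair (0.47).

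Other genes well above background on all 4 arrays, next in order of p and with no overlap between the groups, did not pass the threshold. Above the median gene stood HCN2, a pacemaker channel (4.54 relative to the median gene, SE 0.54), DUX4L4, a copy of the DUX4 repeat (4.47, SE 0.53), and EN2, a homeobox factor (4.34, SE 0.52), all at adjusted p = 0.0661. GALR3, a galanin receptor, stood at 3.85, C1orf229 at 4.03 and VPS9D1 at 3.64. CALY, SFTA1P and SNRNP70, a core protein of the U1 spliceosomal particle, stood at 4.61, 4.63 and 3.41 (adjusted p from 0.0825 to 0.0864 for these 6). Below the median gene stood FAM118A (-4.28), COX6B2, a testis isoform of a cytochrome c oxidase subunit (-4.29), FUZ, a planar cell polarity protein (-3.94), ZNF2 (-3.47), POLR2J2 (-3.41), TTC28 (-3.38), GBP6, a guanylate-binding protein (-3.32), ACBD7 (-2.96) and RAB12, a small GTPase (-2.77), all at adjusted p = 0.0864. The probes of FAM118A, COX6B2, ZNF2 and ACBD7 match the strand opposite to the Alu repeat.

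Other probes of the same genes often gave other values. The second tested probe of VPS9D1 gave a log2 difference of 0.22 (SE 0.47), that of CALY -0.19 (SE 0.50) and that of SFTA1P -0.60 (SE 0.50), each before the median gene is subtracted. For FAM118A the further probes gave 0.28 and -0.51, for ZNF2 0.14, for RAB12 0.89 and for COX6B2 -1.07. The 3 further probes of TTC28 gave 0.17, -0.42 and 0.00.

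Of 3645 non-coding transcripts tested, 2 were higher (C18orf23 and XLOC_002736) and 1 was lower (XLOC_002730) in infected cells. At an unadjusted p below 0.05, 206 stood higher and 313 lower. The transcripts that follow did not pass the threshold. RNA28SN5, the large-subunit ribosomal RNA, was at 9.46 ± 0.30 in infected and 5.71 ± 0.79 in mock cells (SD, n = 2 each), 4.0 above the median gene (adjusted p = 0.0825). RNA18SN5, the small-subunit ribosomal RNA, stood at 5.50 (adjusted p = 0.0864), with an SD of 1.56 in infected and 1.57 in mock cells. LOC100526771 stood at 4.49 and SNHG33, a small nucleolar RNA host gene, at 3.17. After a correction for probe GC content SNHG33 stood at -0.02, but the brightest probe was picked again there. That value may therefore come from another probe of the gene. The 4 further tested probes of SNHG33 gave log2 differences of 2.22, 1.53, 2.19 and -0.46, and the 3 further ones of RNA28SN5 gave 5.46, 4.0 and 4.03, before the median gene is subtracted. On the lower side, XLOC_013994 stood at -3.83, MIR23AHG, the host transcript of a microRNA cluster, at -3.32, and TNS2-AS1, an antisense transcript, at -3.23. SNAR-G1, a small NF90-associated RNA, stood at -3.13, while its other tested probe gave a log2 difference of 1.19 (SE 0.54) on the same scale as those probes. LOC100509105 stood at -3.00. The probes of TNS2-AS1 and MIR23AHG match the strand opposite to the Alu repeat.

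A few more genes were well above background in 1 group only, without passing the threshold. A_33_P3389578 and GRAMD1A, a membrane sterol transporter, were above background on both infected arrays and on neither mock array. On the scale used they were at least 7.8-fold and 4.3-fold higher in infected cells (adjusted p = 0.0825 and 0.0839). Relative to the median gene, A_33_P3389578 ran from 1.47 to 4.49 and GRAMD1A from 1.03 to 4.2 over the settings. AGXT2L2 and CFAP418-AS1 were above background on the mock arrays alone. On the same scale they were at least 18-fold and 6.1-fold lower in infected cells (adjusted p = 0.0572 and 0.0825). Over the settings AGXT2L2 ran from -4.88 to -1.46 and CFAP418-AS1 from -3.38 to -0.54 relative to the median gene. In all, 690 genes were well above background on both infected and neither mock array, and 31 the other way round, with mock 2 the dimmest array.

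Signal of probes for repeats and ribosomal RNA differed between the groups as classes. The 42 tested probes on the strand opposite to the Alu repeat had median log2 values of 0.26 and 0.50 on HCV 1 and HCV 2, 3.11 on mock 1 and 5.0 on mock 2. Both infected arrays were below both mock arrays for 39 of them, where chance gives 16.7% and 33.7% of all genes lay below in this sense. The 46 probes on the Alu strand had medians of 5.44 and 4.54 in infected and 2.63 and 3.04 in mock cells, and 34 of them were above in both infected arrays. The 6 ribosomal RNA probes had medians of 9.26 and 9.0 in infected cells, 2.02 on mock 1 and 6.17 on mock 2. No single probe of these classes passed the threshold (smallest adjusted p = 0.0921, limma over 24895 probes). No called gene was measured by a probe of these classes. Leaving the classes out could therefore hardly change the counts, which stayed at 5 higher and 2 lower. Ribosomal RNA probes were taken by gene name, not by sequence, so ribosomal sequence under another name was not looked for.

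**Figure D2:**
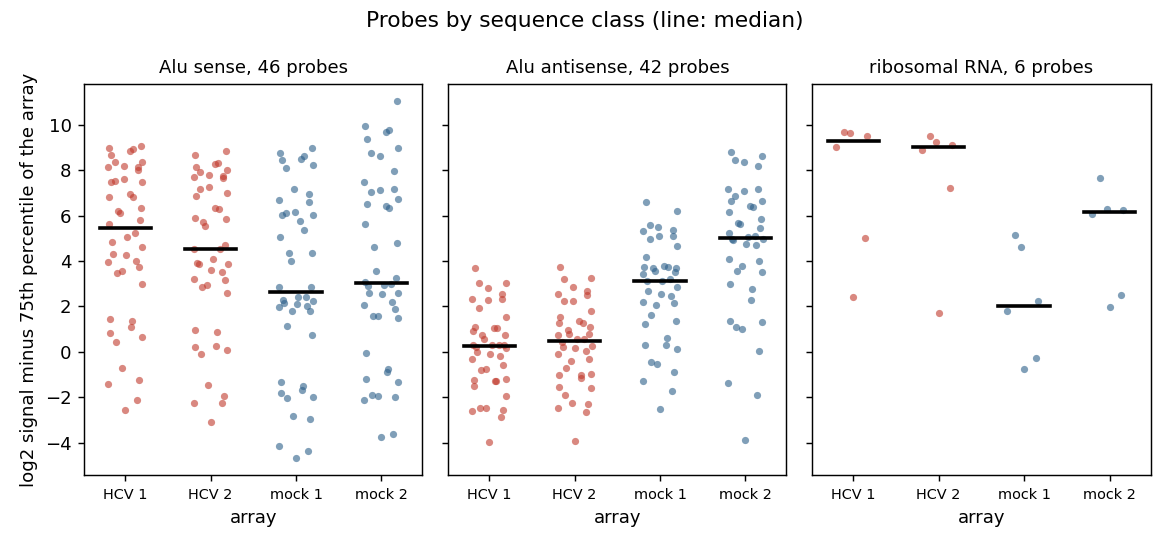
Scaled log2 signal (vertical axis) on each array for tested probes on the Alu strand, on the opposite strand and for ribosomal RNA, with 1 point per probe and a line at the median. The antisense medians are 0.26 and 0.50 on the infected arrays against 3.11 and 5.0 on the mock arrays, while the ribosomal RNA medians are higher on the infected arrays.

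The gene lists, 31 in number and fixed beforehand, cover antiviral signalling, stress, lipid and energy metabolism, the cell cycle and cell types. No member of any list passed the threshold over all genes, and none of the 30 lists with at least 3 tested members passed with camera (smallest adjusted p = 0.166). Adjusted over their list alone, 8 members passed. That adjustment does not correct across lists, and a member of a short list can pass with a larger p than one of a long list. At an unadjusted p below 0.05, camera placed 4 lists lower. With an estimated correlation no list passed either (smallest adjusted p = 0.997), while fry, which does not compare with other genes, called 1 list in one direction and 5 in mixed directions. Without a filter on dim probes camera called 6 lists Up, namely ATF4 and CHOP targets, cholesterol biosynthesis, HCV entry factors, HCV replication and assembly factors, oxidative phosphorylation and histones. With an estimated correlation as well none of these calls held (adjusted p = 0.918 for each).

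Interferon genes and their targets showed no call. Of 32 interferon-stimulated genes tested, 0 passed over all genes and 0 adjusted over the list alone. Their median was -0.12 relative to the median gene (camera adjusted p = 0.689, Down), or -0.29 without HCV 1 and -0.26 without HCV 2. Both infected arrays were below both mock arrays for 14 of them and above for 4. Across all genes 33.7% lay below and 17.5% above in this sense. The members with the smallest p were MX1, a GTPase that blocks viruses (-1.18, SE 0.45), RIGI, the RNA sensor defective in this line (-1.01, SE 0.45), IFI27 (-1.0, SE 0.45) and TAP1, a peptide transporter for antigen presentation (-1.05, SE 0.51, and -0.63 without mock 2), with adjusted p from 0.217 to 0.291. The 13 viral RNA sensing genes had a median of -0.35 (adjusted p = 0.608), or -0.09 without HCV 1, -0.52 without HCV 2, -0.05 without mock 1 and -0.61 without mock 2. TRIM25, which ubiquitinates RIG-I, stood at -1.12, the adaptors TICAM1 and STING1 at -0.59 and -0.38, and DHX58, a RIG-I-like helicase above background on 1 of 2 mock arrays, at -1.36. Left-out arrays moved STING1, to -0.07 without HCV 1, -0.72 without HCV 2, -0.61 without mock 1 and -0.21 without mock 2. Of the type I and III interferons only 2 genes could be tested, too few for a list test. IFNL2 stood at -0.39 (SE 0.50, and -0.83 without mock 1 and -0.01 without mock 2). IFNL1 was above background on the infected arrays alone and too dim there for a fold, but it stood at only 0.08 (SE 0.63). Its log2 values overlapped, at -2.48 on HCV 1, -3.75 on HCV 2, -3.56 on mock 1 and -2.32 on mock 2.

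With camera, NF-kB targets and inflammatory cytokines had the smallest p of all lists. Their median was -0.48 relative to the median gene over 24 tested members (camera p = 0.00553, adjusted p = 0.166, and p = 0.0964 with an estimated correlation). Both infected arrays were below both mock arrays for 13 members. Adjusted over the list alone, 2 members were lower: LTB, a lymphotoxin subunit (-2.20, SE 0.47), and SAA2, an acute phase protein (-2.09, SE 0.58). The differences tested, before the median gene is subtracted, were -2.46 for LTB and -2.34 for SAA2. The chemokines CXCL1 and CXCL3 stood at -1.81 (SE 0.76) and -1.49 (SE 0.73), or -0.60 and -0.43 without HCV 1 and -3.04 and -2.57 without HCV 2. The list passed with a variance trend (adjusted p = 0.0447), with every probe taken by itself (0.0473), without mock 2 (0.0459) and without HCV 2 (0.00217), where the adjusted p ran from 0.00217 to 0.904 over all settings, and its median kept its sign under every scaling tried, from -0.48 to -0.29. With an estimated correlation none of these 4 calls held (adjusted p from 0.922 to 0.996). The median was -0.13 without HCV 1 and -0.82 without HCV 2.

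Genes of the endoplasmic reticulum and of the stress response were split. The 26 ER chaperone and degradation genes had a median of -0.28 (camera p = 0.0123, adjusted p = 0.185, and p = 0.401 with an estimated correlation), and both infected arrays were below both mock arrays for 14 members and above for 0. EDEM1, which takes misfolded glycoproteins to degradation, stood at -1.30 (SE 0.47), CALR and P4HB, a chaperone and a disulfide isomerase, at -1.20 (-0.69 without mock 2) and -1.16, and HERPUD1 at -1.03. No member passed over all genes or adjusted over the list alone. The list passed with a variance trend (adjusted p = 0.0447), without mock 2 (0.0459) and without HCV 2 (0.0288), where the adjusted p ran from 0.0288 to 0.941 over all settings, but in none of these with an estimated correlation (adjusted p from 0.922 to 0.996). Its median was -0.02 without HCV 1 and -0.58 without HCV 2. For P4HB the mean of its probes gave 0.15 instead. The 32 ATF4 and CHOP targets had a median of -0.02, which ran to 0.15 over the scalings and from -0.11 without mock 2 to 0.22 without HCV 2, and a mean of 0.32 (adjusted p = 0.757, Up). Among them DDIT3, which encodes CHOP, stood at 2.48 (SE 0.93), with 1 of 2 mock arrays above background and values of 0.87 without mock 2 and 4.04 without mock 1. The members SLC3A2, AARS1 and PCK2 stood at 1.86 (1.11 without mock 2), 1.71 and 1.67. None passed over all genes or adjusted over the list alone.

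Lipid metabolism, on which HCV assembly depends, held values on both sides of the median gene. Cholesterol biosynthesis (25 genes) had a median of 0.21 (adjusted p = 0.689), which was -0.18 without HCV 1 and 0.37 without HCV 2. MVD and TM7SF2, enzymes of the pathway, stood at 2.59 (SE 0.59) and 2.39 (SE 0.61), TM7SF2 with 1 of 2 mock arrays above background and a value of 1.52 without mock 2, while HMGCS1 and SQLE stood at -1.10 and -1.0, SQLE at -0.60 without HCV 2. The 30 genes of fatty acid and triglyceride synthesis and lipid droplets had a median of 0.01, from -0.06 to 0.02 over the scalings and from -0.09 without mock 2 to 0.25 without HCV 2 (adjusted p = 0.826), and 2 members were higher adjusted over the list alone. These were DGAT2, which makes triglycerides (3.61, SE 0.66, 1 of 2 mock arrays above background), and PNPLA2, the lipase that breaks them down (2.91, SE 0.55). ELOVL5 and SCD, which elongate and desaturate fatty acids, stood at -1.65 (-1.04 without mock 1) and -1.26. Apolipoproteins and VLDL assembly (17 genes) had a median of -0.21 (camera adjusted p = 0.757), or -0.11 without HCV 1, -0.35 without mock 1 and -0.14 without mock 2. It was the list that fry called lower (adjusted p = 0.0393), a test that does not take off the shift of the median gene. APOE, APOA1 and APOA4 stood at -0.90 (SE 0.61), -0.73 (SE 0.45) and -0.71 (SE 0.47), and LCAT at 2.32 with 1 of 2 mock arrays above background. APOE stood at -1.76 without mock 1 and -0.09 without mock 2, LCAT at 1.24 without mock 2. Of 24 genes of fatty acid oxidation (median -0.21, or 0.02 without HCV 2 and -0.09 without mock 1, mean 0.09, camera adjusted p = 0.994, Up), ACADS was higher adjusted over the list alone (2.90, SE 0.56, 1 of 2 mock arrays above background), while CPT2, a carnitine transferase, stood at 1.53, VNN1 at -1.04 and FABP1, the liver fatty acid-binding protein, at -1.19 (-0.72 without mock 2).

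**Figure D3:**
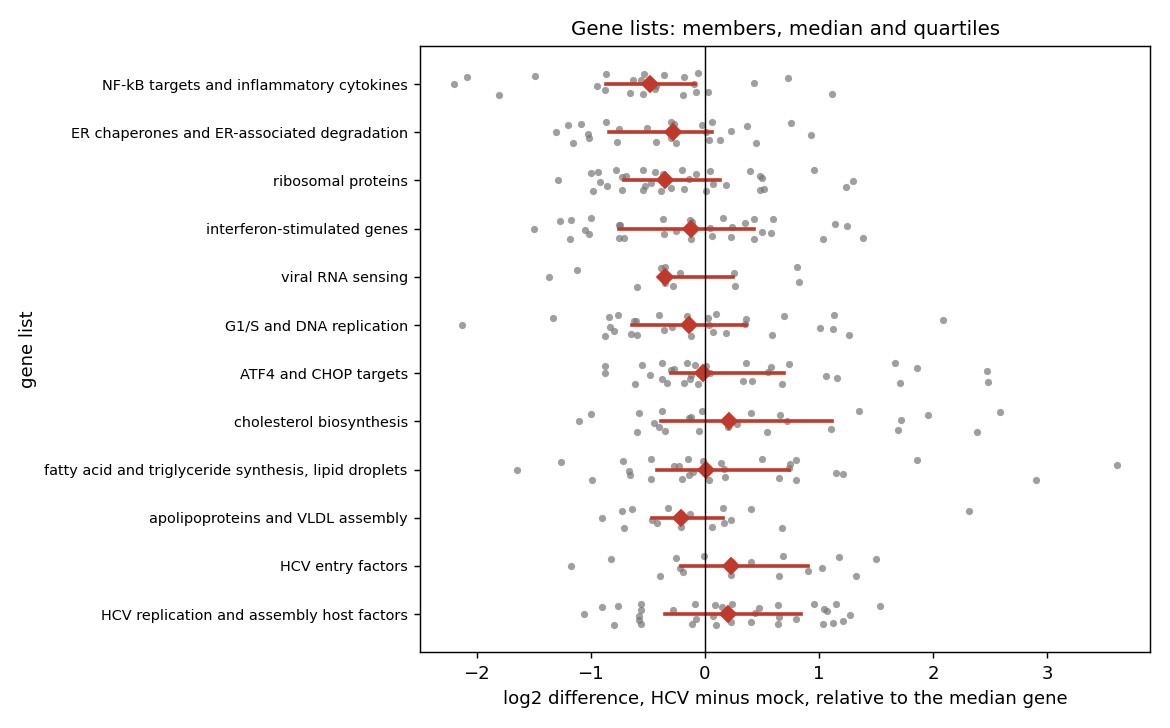
Log2 difference between infected and mock cells relative to the median gene (horizontal axis) for the tested members of 12 gene lists, with 1 point per gene, a diamond at the list median and a line between the quartiles. The list medians run from -0.48 for NF-kB targets and inflammatory cytokines to 0.23 for HCV entry factors, and single genes spread far wider.

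Energy and growth lists also showed no call over all genes. Glycolysis and hypoxia genes (26) had a median of -0.25 (adjusted p = 0.689), which was 0.08 without HCV 1, 0.01 without mock 1, -0.5 without mock 2 and -0.75 without HCV 2. HK2, the glucose transporter SLC2A1 and the prolyl hydroxylase P4HA1 stood at -1.62, -1.55 (-0.86 without HCV 1) and -1.22 and the phosphofructokinase PFKL at 2.64. Oxidative phosphorylation genes (30) had a median of 0.15 (adjusted p = 0.757), or 0.39 without HCV 2 and up to 0.36 over the scalings. In the G1/S list (30 genes, median -0.14, or -0.28 without mock 2, adjusted p = 0.689), cyclin CCNE2 stood at -2.13 (SE 0.57) and E2F1 at -0.88, while the DNA polymerase gene POLE, with 1 of 2 mock arrays above background, stood at 2.09 (SE 0.53). The G2/M list (30 genes) had a median of 0.14 (adjusted p = 0.826), which was -0.15 without mock 2 and 0.29 without mock 1. The kinase PLK1, with 1 of 2 mock arrays above background, and the phosphatase CDC25B stood at 2.23 (1.27 without mock 2) and 1.95, the centromeric histone CENPA and BIRC5 at -1.26 and -1.06. Fry called both cell cycle lists in mixed directions (adjusted p = 0.0294 and 0.0452), as it did the lipid droplet list (0.0452), HCV entry factors (0.0452) and HCV replication and assembly factors (0.0337). Ribosomal protein genes (35) had a median of -0.35 (camera p = 0.0438, adjusted p = 0.353, and p = 0.606 with an estimated correlation), a median that ran from -0.39 to 0.14 over the scalings and so changed sign, and was -0.19 without mock 2. With a variance trend that list passed (adjusted p = 0.0447, with a range of 0.0447 to 0.808 over all settings), but not with an estimated correlation as well (adjusted p = 0.98).

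Host factors of HCV itself lay on both sides of the median gene. The 17 entry factors had a median of 0.23 (quartiles -0.21 and 0.90, adjusted p = 0.689), or 0.15 without mock 2. The lectin CLEC4M, with 1 of 2 mock arrays above background, stood at 1.33 and EPHA2, a receptor kinase, at 1.5, while IFITM1, an interferon-induced membrane protein, stood at -1.17 and OCLN, the tight junction protein occludin, at -0.82. EPHA2 stood at 0.98 without HCV 2 and IFITM1 at -2.01 without HCV 1 and -0.35 without HCV 2. OCLN stood at -0.43 without HCV 1, -1.24 without HCV 2, -0.40 without mock 1 and -1.29 without mock 2. The 36 replication and assembly factors had a median of 0.20 (quartiles -0.35 and 0.84, adjusted p = 0.757), with both infected arrays above both mock arrays for 11 members and below for 13. That median was 0.42 without mock 1 and 0.07 without mock 2. The cyclophilin PPIB stood at 1.54, the chaperone HSP90AA1 at -1.06, or -0.14 with the mean of its probes, VAPA at -0.80, or -0.51 without HCV 2, and SYNCRIP at -0.90. SYNCRIP stood at -0.42 without HCV 1, -1.40 without HCV 2 and 0.29 with the mean of its probes. Hepatocyte proteins and transcription factors (30 genes) had a median of 0.03 (adjusted p = 0.829), which ran from -0.19 without HCV 1 to 0.41 without HCV 2. With 1 of 2 mock arrays above background, the transcription factors HNF4A and FOXA3 stood at 1.98 and 1.87 and the heme-binding protein HPX at 2.33, or 1.1 without HCV 1 and 3.55 without HCV 2, while PCK1 stood at -1.17.

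The remaining lists gave adjusted p from 0.353 to 0.994 with camera. Endothelial and biliary markers (9 genes) had a median of -0.26 (camera p = 0.0471, adjusted p = 0.353, and p = 0.314 with an estimated correlation). That median was -0.42 without HCV 1, -0.62 without mock 1 and -0.41 without mock 2. Adjusted over the list alone 2 genes were lower, SOX9 and CFTR, at -1.45 each, or -1.71 each before the median gene is subtracted. Over all genes their adjusted p was 0.164 and 0.198 (limma). VWF stood at -0.67. SPP1, with 1 of 2 mock arrays above background, stood at -0.65, or 0.23 without mock 1 and -1.57 without mock 2. Leukocyte markers (11) had a median of -0.11 (mean 0.15, camera Down) and fibroblast and stellate cell markers (4) of 0.64, which was 0.02 without HCV 1, 1.22 without HCV 2, 1.12 without mock 1 and 0.10 without mock 2. In the epithelial-mesenchymal list (23 genes, median 0.05, mean 0.12, camera Down), CDH2, N-cadherin, was lower adjusted over the list alone (-1.94, SE 0.47). Its difference before the median gene is subtracted was -2.20. CDH1, E-cadherin, stood at -1.26, ID1 at -1.08 and TGFB1, with 1 of 2 mock arrays above background, at 2.16 (1.42 without HCV 1). The NRF2 list (27, median -0.09, mean 0.18, camera Up) held GCLM at 2.18, measured by a probe on the Alu strand, and PRDX1, GPX1 and TALDO1 at -1.51, -0.90 (-0.58 without mock 2) and -0.83. Medians were -0.24 for the heat shock response (19), -0.21 for autophagy (23, mean 0.02), -0.12 for immediate early genes (25), 0.01 for p53 targets (22, camera Down), 0.56 for replication-dependent histones (17) and -0.17 for reference genes (17). Without mock 1 the heat shock and autophagy medians were both -0.04 and that of histones was 0.20, without mock 2 the autophagy median was -0.34, and without HCV 1 those of autophagy, histones and reference genes were -0.10, 0.09 and -0.26. Without HCV 2 autophagy stood at -0.11, immediate early genes at -0.03 and reference genes at -0.04. Over the scalings the sign changed for the leukocyte list (-0.20 to 0.04), the epithelial-mesenchymal list (-0.06 to 0.05), the NRF2 list (-0.09 to 0.01), the heat shock list (-0.24 to 0.07) and p53 targets (-0.08 to 0.13). With 1 array left out the sign changed for the leukocyte list (-0.63 without mock 1, 0.09 without mock 2), the NRF2 list (-0.07 without mock 2, 0.12 without HCV 2), p53 targets (0.27 without mock 1, -0.26 without mock 2) and the epithelial-mesenchymal list (-0.01 without HCV 2, 0.19 without mock 1 and 0.11 without mock 2). The 11 metallothioneins had a median of 0.23, which was 1.28 without mock 1 and -0.94 without mock 2. The 35 well-studied long non-coding RNAs had a median of 0.07, or -0.12 without HCV 1, 0.21 without HCV 2, -0.02 without mock 1 and -0.01 without mock 2, with MALAT1 at 1.90, SNHG7 at -1.21 (-0.77 without mock 1, 0.09 with the mean of its probes), HOTAIR at -1.30 (-0.74 without mock 2, 0.03 with the mean of its probes) and CASC2 at -2.18 with 1 of 2 infected arrays above background.

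Other settings moved many of these values. Over the scalings, medians that kept their sign moved by over 1.5 times for 19 lists. Among them cholesterol biosynthesis ran from 0.08 to 0.40, HCV entry factors from 0.21 to 0.54, replication and assembly factors from 0.20 to 0.36, hepatocyte proteins from 0.02 to 0.38, apolipoproteins from -0.28 to -0.01, fibroblast markers from 0.14 to 0.88 and histones from 0.25 to 0.56. Without a filter on dim probes, which adds many dim genes to the median gene, 12 of 30 list medians went from below to above it, ER chaperones to 0.06 and the heat shock response to 0.21 among them. Of 76 named list members, 34 stood closer to 0 by over 1.5 times after normexp with quantile scaling, among them LTB (-1.17), DGAT2 (1.5), ACADS (0.97) and CFTR (-0.58), each of which had passed adjusted over its list alone. With the mean of a gene's probes 17 members moved so. PNPLA2 then stood at 1.49, CDH2 at -0.87, CXCL1 at -0.79, ELOVL5 at -0.70, MALAT1 at 0.66, PCK2 at 0.58, PRDX1 at -0.45, GPX1 at -0.39, APOA1 at -0.17 and TICAM1 at -0.17.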

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

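Cyclic loess, the GC correction, leaving out probes matching Alu or ribosomal RNA and the crossed pairs were chosen after seeing the data. In every setting each called gene differed by at least 2-fold, so the counts below hold for both kinds of count. Where the counts moved, the cause was not tested. The 5 higher and 2 lower genes gave the same counts with the series matrix, with a robust prior and without probes matching Alu or ribosomal RNA. There were 0 higher and 0 lower genes, non-coding ones included, under normexp and quantile scaling, quantile scaling, median centring and no filter on dim probes (36599 genes tested), with limma in each case; at an unadjusted p below 0.05 the counts were 1601 higher and 1404 lower, 1671 and 1055, 1462 and 1196, and 756 and 1664 in that order. Under cyclic loess 1 was higher and 0 were lower, with 0 non-coding each way. Only probes above background on all 4 arrays gave 43 and 50 (non-coding 4 and 10) over 14907 genes, a variance trend gave 168 and 174 (non-coding 19 and 32), and the GC correction 35 and 30 (non-coding 5 and 7). Every probe by itself gave 6 and 4 (non-coding 2 and 3), and the mean of a gene's probes gave 5 and 3 (non-coding 1 and 1). Of the 7 main calls, 7 were also called with the trend and with the GC correction, 5 with the filter on all 4 arrays, 6 with the mean of probes and 1 with cyclic loess.

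Leaving out 1 array gave 46 to 631 higher and 50 to 674 lower genes, and 10 to 81 higher and 10 to 253 lower non-coding transcripts; the lone array left in a group is then assumed to vary like the other group, and all 7 main calls were among them each time. The lists called ran from 0 to 3 in these fits, and 0 with an estimated correlation (smallest adjusted p = 0.922). Lists called by camera numbered 0 in the main setting, 6 without a filter on dim probes (ATF4 and CHOP targets, cholesterol biosynthesis, HCV entry factors, HCV replication and assembly factors, oxidative phosphorylation and histones, all Up), 1 with every probe by itself, and 3 with a variance trend; with an estimated correlation in the same settings 0 of these calls held (adjusted p = 0.918, 0.99 and 0.98). With fry in one direction 1 list was called. With the replicate number as a block, 410 genes were higher and 256 lower (non-coding 71 and 87), and 0 lists were called; the 7 main calls were among these genes. Arrays of the same number deviated from their group means with a correlation of -0.114 over genes, and arrays of different number with 0.114, its opposite by construction, so this check cannot settle a pairing, and the labels state none. Crossed pairing gave 469 higher and 306 lower genes (non-coding 79 and 97).

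Of the 114 features named with a log2 difference, 108 kept their direction in every setting. A variance trend, a robust prior, the replicate block, crossed pairs and median centring cannot change these differences. The series matrix holds nearly the same values. Unchanged directions in those settings are therefore no evidence of stability. P4HB, HOTAIR, SYNCRIP and SNHG7 reversed with the mean of their probes (0.15, 0.03, 0.29 and 0.09 relative to the median gene), and SNHG33 reversed with the GC correction (-0.02). For SNHG33 the brightest probe was picked again after that correction, so the value may come from another probe. SPP1 ran from -1.57 to 0.23 with 1 array left out, the latter without mock 1. Signal over background was lowest on mock 2, where 40.86% of spots were well above background. Counts of calls with 1 array left out rest on the spread of the other group alone, so they do not show which array limits the calls.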

Other observations

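The tests of the Alu gap without mock 2 and of bright other probes of a gene were chosen after their values had been seen in part or whole. Metallothioneins, zinc- and copper-binding proteins that respond to metals and stress, differed between the mock arrays. Their 11 genes had median log2 values of 4.85 on mock 1 and 1.75 on mock 2, with 3.10 on HCV 1 and 3.31 on HCV 2, and 10 of them were higher on mock 1 than on mock 2. Relative to the median gene the list stood at 1.28 without mock 1 (camera adjusted p = 0.004, Up) and at -0.94 without mock 2 (adjusted p = 0.00852, Down), so its sign rests on which mock array is kept. With an estimated correlation neither call held (p = 0.229 and 0.24, adjusted p = 0.993 and 0.996).

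Probes on the strand opposite to the Alu repeat were lower, and probes on the Alu strand higher, in infected cells, a gap of -5.0 between their medians; 21 of the 60 lowest probes and 0 of the 60 highest were antisense to Alu. Correcting each array for probe GC content left a gap of -5.08. A sequence and its reverse complement have the same GC content, so this correction could hardly change the gap and decides nothing. Leaving out mock 2 left -4.32, which argues against the dim mock 2 array as the whole cause. Another candidate explanation is more labelled RNA of the opposite strand on the mock arrays for all transcripts. In 39 probe pairs that cover one sequence on both strands, without Alu or ribosomal matches and with a bright partner, the dimmer probe had a median of -0.85 relative to the median probe (quartiles -2.04 and -0.30), against -0.19 for the bright partners, and 27 of 39 lay below in both infected arrays while 1 lay above. That median falls between the bounds set (-1 and -0.5), so this explanation stays open, as does an effect of infection, which was not tested and which the groups cannot separate from a difference in RNA preparation.

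Ribosomal RNA probes stood 4.19 above the median probe in infected cells. The mock arrays differed widely, with medians of 2.02 on mock 1 and 6.17 on mock 2, against 9.26 and 9.0 on the infected arrays. Both infected arrays were above both mock arrays for 5 of the 6 probes, and 4 of the 6 were for RNA28SN5. The RNA5-8SN5 probe gave a log2 difference of 1.19 (SE 0.93), with overlapping groups. After the GC correction the ribosomal RNA probes stood at 4.08, which argues against GC content as the cause. If RNAs without a poly(A) tail were labelled more in general on the infected arrays, small nuclear and nucleolar RNAs should stand high too, provided the columns kept them. Their 191 probes had a median of 0.06 (quartiles -0.65 and 0.63). Whether the columns kept such small RNAs was not tested, so more labelling of longer RNAs without a poly(A) tail stays open. The XLOC_013994 probe, at -3.83, lies 1245 bases from the RNA18SN5 probe (5.50) on the same unplaced contig and on the opposite strand, the same opposition of strands as for Alu. An effect of infection on ribosomal RNA was not tested and stays open.

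Large differences were often not shared by other probes of the same gene. Of 203 genes whose main probe differed by 3 or more, the other tested probes shared at least 0.5 of the difference in 12 of 51 cases. The main probes were picked by the size of their own difference, which by itself makes smaller values in other probes likely. Over 2344 pairs of probes more than 100 bases apart in one transcript, not picked in this way, the log2 differences correlated with r = 0.21. Dimness of the other probe could not be settled, since of the 20 bright ones 35% shared the difference. Distance along the transcript is in line with part of it: the gap between 2 probes rose with their distance (Spearman correlation 0.35 over 2786 pairs), although by less among pairs more than 100 bases apart (0.18). Different transcript ends in infected cells and differences in RNA length between arrays may both give such a relation, and they cannot be separated here.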
